A study of Mus musculus with 3 samples.

How the data were processed

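The series holds 3 arrays of mouse RNA, each read once: FULA 1 lung adenocarcinoma cells, lung after saline and lung after urethane. RNA was extracted with Trizol and spin columns, and biotin-labelled, per the labels' protocols. The deposited table holds 1 log2 value per probe set and array for 41345 probe sets. RMA (robust multi-array average: background correction, quantile normalization and a summary over probes) is named in the submitters' processing notes, and GeneSpring GX 12.5 in the design text. The background setting, the annotation and the set of arrays normalized together are not given in the sources used here. Scanner files were not used here. All 3 columns were used, and 0 columns of other samples were present.

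The columns were not on one scale: the medians were 4.96 on FULA 1, 0.08 on saline lung and 1.22 on urethane lung, and the quantiles followed different curves. No centring per probe set was seen, and the direction of the values is that of log2 signal; what made the scales differ stays unknown. The plan made before the data were examined took the table as deposited and listed quantile normalization as an alternative. Once the scales were seen, the arrays were quantile-normalized over all probe sets to the mean of the 3 sorted columns, with tied values given their mean rank, and the deposited values became the alternative. This exchange departs from the plan. Counts from the deposited values, from the mean quantiles and from the quantiles of the FULA 1 array had all been seen when the text was written. A difference among the lowest values is compressed or stretched by such a step, so percentile ranks on each array, which no monotone scaling changes, are given for a few genes. The most frequent single value was shared by 112 probe sets on FULA 1, 934 on saline lung and 1277 on urethane lung, so low values have little resolution on the lungs. Ties also reached higher values. On the urethane lung Lat, Cyp2b10 and Ces1d shared 2.68 (percentile rank 82.9). There Pdgfra, Des and Chad shared 3.73 (percentile rank 91.3). Differences of such genes are coarse as well.

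Probe sets were named through the platform annotation: 23521 carried 1 gene symbol, 1814 carried several and were not used to name a gene, and 16010 were unnamed here. Symbols were updated by Entrez identifier through the RefSeq gene table of assembly GRCm38.p6, which matched 23328 of the 23521. The array's own build is not given in the sources used here, so no coordinates are given, and the table served only for names and for which genes neighbour each other. A gene's value was the mean of its probe sets, giving 22180 genes, of which 1082 had more than 1 probe set.

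With 1 array per group no test was run and no p-value or standard error is given, and the number of arrays limits the precision. Per comparison, genes were counted as higher or lower at a difference of at least 2-fold (1 on the log2 scale) if the higher of the values compared was at or above the floor, the median of all gene values of the 3 arrays (2.37 after normalization). Gene lists were fixed before the data were examined, as were the size rule, the floor and the rule for named genes: 46 lists, of which 24 hold cell type markers, 18 programmes and 4 checks on sex, time of day and handling. Of their 665 entries 610 were used and 55 were not analysed here. Each list's median difference was placed among the medians of 10000 random lists of the same size, matched on mean expression in 20 bins, as a description of these arrays. A list outside the percentiles 2.5 to 97.5 was taken as standing apart. Named genes were the 10 highest and 10 lowest past the floor in each comparison with the saline lung and the 5 highest and 5 lowest in that of FULA 1 with the urethane lung, without unnamed transcripts, microRNAs, olfactory and vomeronasal receptors and antigen receptor segments. The rule also took the 2 highest and 2 lowest members of each list, and always Scgb1a1, Sftpc, Ager, Foxj1, Cdkn1a, Mki67, Ptprc, Pecam1, Col1a1, Epcam, Xist and Cyp2e1; some other genes of that rule are not reported here. Some members were left out for room. A gene of the neighbour run in the closing section, and Krt7 and Krt19, were named after their values were seen. A bound for a difference whose lower value lay below the olfactory receptor mark, also added then, used the higher value minus the normalized value of the mark on the other array (1.96 on FULA 1, 2.47 on saline lung and 2.44 on urethane lung), and a gene below the mark on both arrays was given no size. List medians are those of the normalized values unless they are said to be held at the mark, where such a gene counted as 0. A list with at least 50% of its members below the mark on both arrays was not assessed.

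Other settings, listed beforehand, were a threshold of 1.5-fold or 4-fold, no floor or one at the 75th percentile, a shift of each array to a common median, subtraction of a lowess curve (span 0.3), an offset of 32 on the linear scale, the probe set with the highest mean, all probe sets as units, unmatched random lists, and other forms of the position comparison. Settings added after the data were seen were the quantiles of the FULA 1 array as the target, a floor at the 95th percentile of olfactory receptor genes, and random lists matched on the lungs. Under scalings other than quantile, list and gene differences are relative to the median difference of all genes, which was 1.09 for urethane against saline, 4.80 for FULA 1 against saline and 3.69 for FULA 1 against urethane as deposited (log2).

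The size rule was tested on simulated data for urethane against saline over 22180 genes, with noise of SD 0.469 and the deposited distortions put back. That SD came from the spread of the measured urethane minus saline differences and was the same at all expression levels. Any real difference between the lungs is part of it, so the false passes are not an independent rate. The simulated lungs were normalized without the FULA 1 array, whose values are spread more widely. Differences were therefore on a narrower scale than in the results, and the gene counts below, false passes included, do not carry over exactly. Of 50 genes planted at 2 on the log2 scale 47 were recovered, and of 50 at 1.5, 37. Of 50 planted at -2 only 34 were recovered and of 50 at -1.5 only 18, with median measured differences of -1.23 and -0.92. The cause of the lower recovery was not tested. Among 12039 unplanted genes 194 passed. The list percentile was checked on the measured urethane minus saline differences, with genes past the floor and random lists matched on the lungs. Of 100 random lists of 15 genes shifted by 0.4, 83 exceeded the percentile 97.5, and 8 of 100 unshifted lists fell outside the central range. The list calls in the results were matched on the 3 arrays, so these rates do not carry over exactly. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, statsmodels 0.14.6 and matplotlib 3.10.9 were used.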

Results

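RNA levels were measured on 3 mouse whole-transcript arrays, 1 for the lung of FVB mice after an injection of saline, 1 for the lung of FVB mice after an injection of urethane, and 1 for cultured FULA 1 cells. FVB is an inbred mouse strain that is prone to lung tumours. Urethane (ethyl carbamate) is a carcinogen whose metabolites bind DNA and which gives lung adenomas in mice; the urethane lung was taken 1 week after the injection. FULA 1 is a mouse lung adenocarcinoma line, per the labels. How many mice stood behind each lung array, and when the saline lung was taken, are not given in the sources used here. The comparisons ask how the lung differed after the carcinogen, how the tumour line differed from each lung, and whether the urethane lung differed from the saline lung in the direction of the line. There were no replicates, so no difference could be set against a replicate spread, and every value below compares these arrays rather than the conditions.

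The 3 deposited columns did not lie on one scale. The median over 41345 probe sets was 4.96 on the FULA 1 array, 0.08 on the saline lung array and 1.22 on the urethane lung array (log2), while the curves met at their maxima. Actb, which encodes the cytoskeletal protein beta-actin, was listed at 11.01 on FULA 1, 7.15 on saline lung and 7.12 on urethane lung. The 1105 olfactory receptor genes, which few cells outside the nose transcribe, served as a mark of background, a choice made after the data were seen. On FULA 1, 12900 of 22180 genes lay above the 95th percentile of these receptors, against 11011 on the saline lung and 10858 on the urethane lung. Across genes, which are not independent replicates, the Spearman correlation was 0.932 between the lungs, 0.743 between FULA 1 and the saline lung and 0.771 between FULA 1 and the urethane lung. The differences below were taken after quantile normalization, and fold sizes depend on that step. Some genes held the same deposited value on all 3 arrays, among them Calcrl (6.81), Tppp3 (6.39) and Emcn (3.96). Their differences come from the normalization alone, and why the values are equal was not tested. Where the lower of the values compared lay below this mark the size is not exact, and the bound given puts the mark in place of that value. A list with at least 50% of its members below the mark on both arrays compared was not assessed in that comparison, a rule also chosen after the data were seen.

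**Figure D1:**
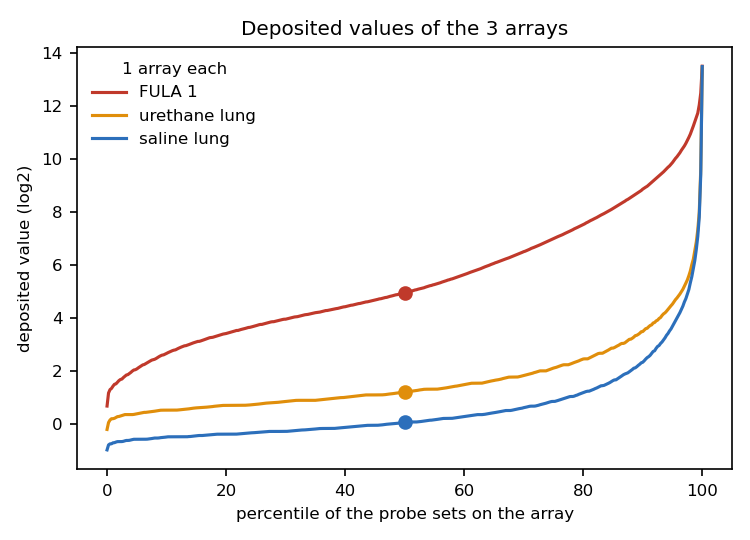
Deposited log2 value (vertical axis) at each percentile of the 41345 probe sets of an array (horizontal axis), with 1 line per array and a point at the median. The FULA 1 line lies above both lung lines over most of its length, with medians of 4.96, 1.22 and 0.08, and the lines meet at the maximum.

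The lungs of saline and urethane mice were close to each other in their cell type markers. Scgb1a1, the secretoglobin of club cells, differed by 0.03 (log2, urethane minus saline), and Ager, a marker of alveolar type I cells, by 0.15. Sftpc, the surfactant protein C gene of alveolar type II cells, differed by 0.25; all 3 differences turned negative when each array was only shifted to a common median. Genes of the immediate early and heat shock responses were higher in the urethane lung, with a median of 0.46 over 18 measured members. Alveolar type II markers were higher by a median of 0.37 over 15 members, which became -0.17 with the arrays shifted to a common median. Cardiac muscle genes were lower, with a median of -0.40 over 12 members. Targets of p53, the transcription factor activated by DNA damage, had a median of -0.06 over 20 members.

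In all, 409 genes were at least 2-fold higher and 164 at least 2-fold lower in the urethane lung among 12519 genes past the floor. In the simulation 47 of 50 genes planted at 2 were recovered, but 34 of 50 planted at -2. The split therefore cannot be read as a direction of change. The values as deposited gave 5180 higher and 0 lower. The split was 215 higher and 203 lower with the arrays shifted to a common median, 979 and 897 with the quantiles of the FULA 1 array as the target, and 244 and 34 after a lowess curve was subtracted. Among 315 genes with a pair of probe sets past the floor, the pair had the same sign of difference in 169 genes (53.7%), and the median gap between the pair was 0.43 (log2).

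The highest differences belonged to Defa39 at 2.72, Smim22 at 2.61, Cpq at 2.59, Ddx5 at 2.44 and Usp17ld at 2.36. Next came Khnyn at 2.25, Abca3 at 2.23, Notch2 at 2.07, Ddx47 at 2.06 and Anpep at 2.02. Abca3 encodes the lipid transporter of the lamellar bodies in which alveolar type II cells store surfactant, Ddx5 and Ddx47 encode DEAD-box RNA helicases, Notch2 a receptor of the Notch pathway and Anpep the membrane aminopeptidase N. The lowest were Prps1, a phosphoribosyl pyrophosphate synthetase, at -2.31, and Gbp4, an interferon-inducible guanylate-binding protein, at -1.98. Krt6b followed at -1.80, Ly6a2 at -1.68, Spib, a transcription factor of B cells and plasmacytoid dendritic cells, at -1.63. Glycam1 stood at -1.58, Chst13 at -1.58, Prr7 at -1.57 and Kcnma1 at -1.56. Speer8-ps1 also fell among the 10 lowest, but lay below the background mark on both lungs and is given no size. The lower value lay below the mark for 5 of the 10 highest and, with Speer8-ps1, 4 of the 10 lowest, so their order is not exact either: Cpq was higher by at least 2.02, Notch2 by 1.75, Khnyn by 1.68, Defa39 by 1.54 and Ddx47 by 1.18, and Glycam1 was lower by at least 1.13, Spib by 0.68 and Krt6b by 0.50. Defa39, Usp17ld, Gbp4, Ly6a2 and Speer8-ps1 belong to families of near-identical genes, so their values are uncertain. Each of these 20 genes except Kcnma1 rested on 1 probe set.

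Among stress genes, 15 of the 18 immediate early and heat shock members lay above 0, and the list's median exceeded 100% of 10000 random lists matched on expression. Hspa1b, an inducible HSP70 gene, was higher by 1.26 (at least 1.12) and Hsph1, an HSP110 chaperone, by 1.17, whereas Dnajb1 differed by -1.02 and Junb by -0.51. Hspa1b has a near-identical neighbour, Hspa1a, and its value is uncertain for that reason. The Nr1d1 and Per arm of the circadian clock had a median of 0.29 (percentile 95.7), led by Usp2 at 0.90 and Per1 at 0.77, and the Arntl arm one of -0.16 (percentile 32.9), with Npas2 at -0.25 (lower by at least 0.21) and Clock at 0.06. The unfolded protein and integrated stress response had a median of -0.24 (percentile 6.57), with Psat1, a serine synthesis enzyme, at -1.27, but lower by at least only 0.11 with the mark in place of its urethane value.

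Of the epithelial lists, alveolar type II stood at percentile 99.8, with 12 of 15 members above 0, Abca3 at 2.23 and Hc at 0.69 as the highest, and Napsa at -0.42 and Sftpd at -0.23 as the lowest. Alveolar type I markers had a median of 0.01 (percentile 61.3), from Pdpn at -0.69 to Spock2 at 0.72, and club cell markers one of -0.05 (percentile 43.5). Ciliated cell genes had a median of 0.06 (percentile 84.0), with Foxj1, the regulator of motile cilia, at -0.12. Pan-epithelial genes had a median of 0.12 (percentile 88.6), with Epcam at 0.77, while 5 of the 6 basal cell genes lay below the background mark on both lungs, so that list was not assessed. The regulators of lung lineage had a median of 0.02 (percentile 68.6), with Sox9 at -1.14 (lower by at least 0.89); the gastric and gut list was not assessed, with 9 of 17 members below the mark on both lungs.

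Stromal and muscle lists differed mainly in muscle. In the cardiac list, 10 of 12 members lay below 0 and the median stood at percentile 0.450, with the atrial genes Myl7 at -1.34 and Nppa at -1.01. The skeletal muscle median was -0.35 (percentile 2.87, and 2.47 with lists matched on the lungs), with Tnni2 at -0.68, but 5 of its 11 members lay below the mark on both lungs and the median became 0.00 with values below the mark held at it. Endothelial genes had a median of -0.12 (percentile 24.3), from Emcn at -0.83 (equal on both lungs as deposited) to Plvap at 0.80, with Pecam1 at -0.07. Fibroblast and matrix genes had a median of 0.12 (percentile 90.6), with Col1a1, a chain of type I collagen, at 0.71 and Pdgfra at 0.99. The medians were -0.11 for smooth muscle and pericyte (percentile 40.2), -0.17 for mesothelial (percentile 28.4) and -0.10 for mesenchymal transition genes (percentile 33.6).

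Leukocyte lists that could be assessed lay inside the range of random lists with the normalized values, but not all did with values held at the mark. The lists of neutrophils, NK cells, B cells, plasma cells, dendritic cells, mast cells and basophils, and erythroid cells were not assessed, nor was the adipose list. The medians were 0.04 for alveolar macrophages (percentile 74.1), -0.17 for monocytes and interstitial macrophages (percentile 22.1), -0.16 for T cells (percentile 28.7) and -0.20 for thymus genes (percentile 28.3). Held at the mark, the monocyte and interstitial macrophage list (percentile 1.28) and the T cell list fell below the range with medians of -0.08 each, where 92.0% and 94.5% of random lists had a median of 0, so whether these lists stand apart is left open. Single genes went both ways: Lat, an adaptor of the T cell receptor, was at 1.35, Itgax at 0.94 (higher by at least 0.52) and the neutrophil receptor gene Csf3r at 0.78, against the monocyte antigen gene Ly6c2 at -1.23 (lower by at least 1.03), and Retnlg and S100a8, which neutrophils express, at -1.11 and -0.97. Ptprc, the pan-leukocyte antigen CD45, differed by 0.29. Cytokines and chemokines had a median of -0.20 (percentile 8.95), or 0.00 with values held at the mark, with Cxcl13 at -1.13 and Il1b at 0.95. The interferon response stood at -0.03 (percentile 62.4), MHC class II at -0.26 (percentile 12.4), the MHC class I pathway at -0.26 (percentile 5.30) and NF-kB targets at 0.09 (percentile 81.4).

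Lists of DNA damage, proliferation and metabolism had small medians too. Cdkn1a, the p53-induced inhibitor of the cell cycle, differed by 0.26, a sign that turned with the arrays shifted to a common median, and the p53 list stood at percentile 43.7, from Aen at -0.50 to Btg2 at 0.64. The DNA repair list was not assessed. DNA replication genes had a median of -0.11 (percentile 31.2) and G2 and mitosis genes one of -0.23 (percentile 4.96), with Aurkb at -1.01 and Mki67 at -0.55; both medians became 0.00 with values held at the mark. Xenobiotic metabolism had a median of 0.12 (percentile 90.8); Cyp2b10, a cytochrome P450 gene of a family of near-identical genes, was higher by 1.98 (at least 1.54), and Cyp2e1, the main enzyme that activates urethane, by 0.52 (at least 0.30). NRF2 targets had a median of -0.02 (percentile 49.7), with Nqo1 at -0.92 (lower by at least 0.67). The medians were 0.00 for RAS-ERK output (percentile 66.3), -0.10 for glycolysis and hypoxia (percentile 30.7), with Vegfa at 1.05 and Ldha at -0.96, and 0.14 for oncogenes and tumour suppressors (percentile 93.9). In the sex-linked list, not assessed as a whole, Xist was at -0.08. Of the 46 lists 12 were not assessed, and of the other 34, 3 lay outside the central 95% of random lists. Lists of genes that vary independently would give 1.70. Members of 1 list can vary together between single lungs, so more lists may fall outside by chance. With values below the mark held at it 20 of the 46 medians were 0.00, and the sign of 17 of the 46 medians turned under at least 1 other scaling.

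**Figure D2:**
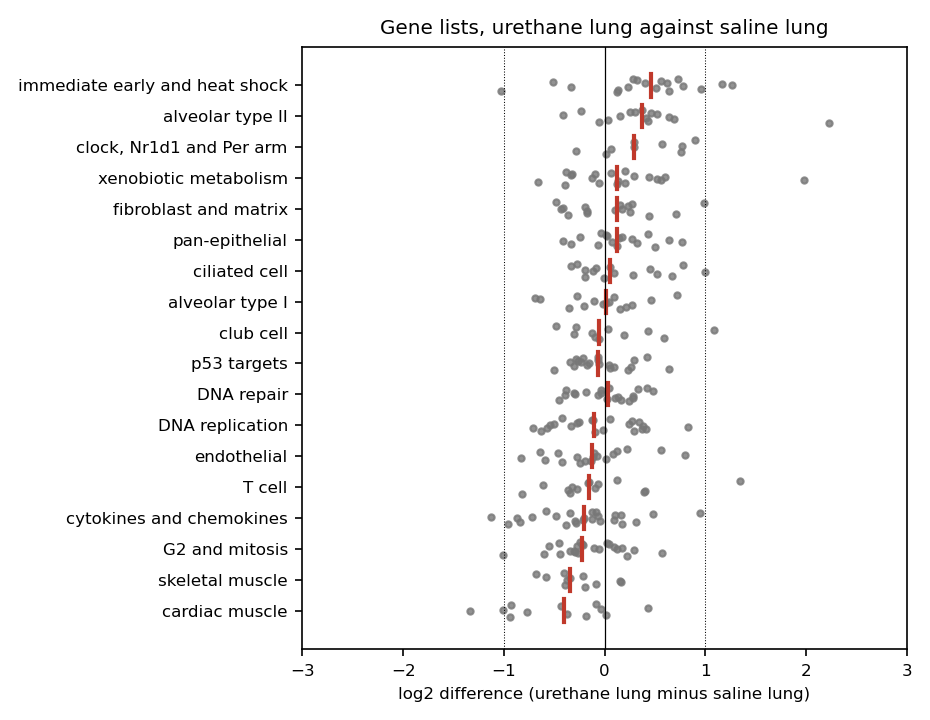
Log2 difference, urethane lung minus saline lung (horizontal axis), of each measured member (grey points) of 18 gene lists, with the list median as a red bar and dotted lines at 2-fold. The medians run from 0.46 for immediate early and heat shock genes to -0.40 for cardiac muscle; the alveolar type II median of 0.37 turned negative with the arrays shifted to a common median, and the DNA repair list shown was not assessed.

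FULA 1 cells lacked the levels of differentiated lung genes seen in the saline lung and were higher in genes of cell division. Cultured cells were set here against tissue of several cell types. In both FULA 1 comparisons, cell composition and culture therefore cannot be told apart from differences in tumour state. Scgb1a1 was at -10.58 (log2, FULA 1 minus saline), or lower by at least 9.88 with the mark as its FULA 1 value, and Sftpc at -8.83; on the FULA 1 array their percentile ranks among probe sets were 20.3 and 53.5, against 99.9 and 99.8 on the saline lung. All 23 measured G2 and mitosis genes were at least 2-fold higher in FULA 1, with a median of 2.93, and all 23 stayed so with values below the mark held at it; Mki67, the proliferation antigen, was higher by 3.10. Endothelial markers had a median of -3.37 and fibroblast markers one of -2.33. Of the 4 simple keratin genes in the pan-epithelial list, Krt8 was at 4.84, Krt18 at 2.89, Krt19 at 1.06 and Krt7 at -0.07.

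Of 13590 genes past the floor, 3073 were at least 2-fold higher and 2994 at least 2-fold lower in FULA 1 than in the saline lung. The values as deposited gave 21703 higher and 20 lower. With the arrays shifted to a common median the split was 7058 higher and 1785 lower, and after lowess 1974 and 3311. Among 378 genes with a pair of probe sets past the floor, 228 pairs (60.3%) had the same sign, and among the 130 of these whose mean was at least 2-fold apart, 115 did.

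The highest differences were those of Clca3b at 7.56, the neutrophil-attracting chemokine Cxcl5 at 6.58, Ranbp3l at 6.48 and Sprr1a, a cornified envelope protein, at 5.79. Anxa10 followed at 5.67, the collagen-binding integrin chain Itga2 at 5.66, the intestinal keratin Krt20 at 5.54, and Ugt2b34 at 5.38. Cpe, which trims peptide hormones, was at 5.21 and Ect2, needed for cytokinesis, at 5.19. Below Scgb1a1 and Sftpc in size came Inmt at -7.62, Cbr2, a carbonyl reductase abundant in lung, at -7.62, Lyz1 at -7.47 and the small nucleolar RNA Rnu3a at -6.98. Cxcl15, a lung chemokine, was at -6.91, Tmem100 at -6.89, Epas1, which encodes HIF-2 alpha, at -6.80 and Fmo2, the lung flavin monooxygenase, at -6.41. The lower value lay below the mark for 8 of the 10 highest and 3 of the 10 lowest, so their order is not exact: Cxcl5 was higher by at least 5.99, Clca3b by 5.88, Itga2 by 5.44, Ranbp3l by 5.28, Ugt2b34 by 4.82, Anxa10 by 4.79, Krt20 by 4.78 and Cpe by 4.50, and Tmem100 was lower by at least 6.50 and Cxcl15 by 6.45. Clca3b, Sprr1a, Ugt2b34, Lyz1 and Rnu3a have close relatives in the genome and are uncertain.

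Markers of club, alveolar type II, alveolar type I and ciliated cells lay below random lists. In the club cell list 9 of 11 members were at least 2-fold lower (median -4.25), and in the alveolar type II list 13 of 15 (median -4.28), with Abca3 at 0.78 the only member above 0. Of 15 alveolar type I markers 10 were at least 2-fold lower (median -2.87), with Ager at -5.21 and Cldn18 at -5.16, while the water channel gene Aqp5 was higher by 2.49. Ciliated cell genes had a median of -1.54, with Tppp3 at -5.28 (equal on all 3 arrays as deposited) and Foxj1 at -2.41. These 4 lists and the regulators of lung lineage, with a median of -1.16 (percentile 0.150), had percentiles under 1; in the last list Hopx was at -3.54 and Tbx5 at -2.94, and Foxa1 at 2.29. The basal cell list was not assessed, since all 6 of its members lay below the mark on both arrays. Pan-epithelial genes had a median of -0.04 (percentile 46.9), whose sign turned under 4 of 5 other scalings; Cldn7 was at -2.23 and Epcam at -0.51, the latter turning positive with the arrays shifted to a common median. Gastric and gut genes had a median of 0.65 (percentile 98.9), with Krt20 at 5.54 and the intestinal cadherin Cdh17 at 4.14 against Tff2 at -1.73. That median became 0.00 with values below the mark held at it, where 78.6% of random lists had a median of 0. Held so, 7 of 17 members were still at least 2-fold higher and 4 at least 2-fold lower. Whether this list stands apart is left open.

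Markers of stroma and vessels were lower in the cultured line, while most lists of blood cells could not be assessed or lay inside the random range. Of 18 endothelial markers 16 were at least 2-fold lower, with Cdh5 at -5.45, Calcrl at -5.32 (equal on all 3 arrays as deposited) and Pecam1 at -4.36. So were 11 of 16 fibroblast and matrix genes, with Dcn at -5.77 and Col1a1 at -3.61. Medians were -1.96 for smooth muscle and pericyte, with Acta2 at -3.63, -1.74 for mesothelial, where Msln was higher by 3.16, -1.71 for cardiac muscle and -1.14 for skeletal muscle. These 6 lists had percentiles under 1, as did T cells (median -1.08, Cd8b1 at -2.03). Ptprc was at -1.44. Inside the random range lay monocytes and interstitial macrophages (median -0.64, percentile 2.75), alveolar macrophages (-0.53, percentile 9.64) and thymus genes (-0.59, percentile 15.3). The alveolar macrophage list held both Fabp4 at -4.17 and Pparg at 3.32. The lists of neutrophils, NK cells, B cells, plasma cells, dendritic cells, mast cells and basophils, erythroid cells and adipose tissue were not assessed; among their single genes S100a8 was at -3.86 and Pax5 at -1.46.

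Genes of the cell cycle and of energy metabolism were higher in FULA 1. Kif11, a mitotic kinesin, was higher by 4.63 (at least 4.07) and Bub1, a spindle checkpoint kinase, by 4.58 (at least 3.59); Cdc20 at 1.26 was the smallest of the G2 and mitosis list. Of 22 DNA replication genes 19 were at least 2-fold higher (median 1.52), with Rrm1 at 3.17 and Mcm7 at 2.96, and of 20 DNA repair genes 11 were (median 1.67), with Brca1 at 2.74, while Mgmt, which removes alkyl groups from guanine, was at -1.43. These 3 lists exceeded 100% of random lists. With values below the mark held at it, 17 DNA replication genes (median 1.27) and 10 DNA repair genes (median 1.02) were at least 2-fold higher. Glycolysis and hypoxia genes had a median of 1.19 (percentile 99.9), with Egln3 at 4.76 and Pgk1 at 3.33. NRF2 targets had a median of 0.72 (percentile 96.2), with Me1 at 2.64, RAS-ERK output one of 0.60 (percentile 95.9), with Myc at 3.34 and Epha4 at 2.90; these 2 lists lay above random lists that were unmatched or matched on the lungs. The unfolded protein and integrated stress response had a median of 0.46 (percentile 85.8), with Psat1 at 3.27. Oncogenes and tumour suppressors had a median of 0.03 (percentile 57.2), with the receptor tyrosine kinase Met at 2.28 and Nras at -1.29, the latter turning positive with the arrays shifted to a common median. The p53 targets had a median of -0.36, inside the range of random lists, with the death receptor Tnfrsf10b at 3.51, Ccng1 at -2.61 and Cdkn1a at -2.53; the list's sign turned under the shift to a common median.

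Genes of antigen presentation, interferon and detoxification were lower than in the saline lung, with its mix of cell types. In the MHC class I pathway 6 of 10 members were at least 2-fold lower (median -1.77, percentile 0.0200), with the immunoproteasome genes Psmb10 at -2.99 and Psmb8 at -2.90. The MHC class II median was -1.01 (percentile 1.58), with H2-Ab1 at -4.39. Of 16 interferon response genes 11 were at least 2-fold lower (median -1.27), with Oasl2 at -3.34, while Ifit2 was higher by 1.12. Xenobiotic metabolism had a median of -1.30, with Fmo1 at -5.28, while Cyp2e1 lay below the background mark on both arrays and is given no size. Cytokines and chemokines went both ways around a median of -0.15 (percentile 40.5; 0.00 with values held at the mark), with 9 of 25 at least 2-fold higher, among them Cxcl3 at 4.45, and 7 lower, among them Ccl5 at -4.44. The medians were -0.40 for NF-kB targets (percentile 14.6), -0.20 for mesenchymal transition genes (percentile 29.4), with Fn1 at 3.70 and Mmp2 at -3.10, and -0.24 for immediate early and heat shock genes (percentile 23.0); these 3 signs turned with the arrays shifted to a common median. The Arntl arm of the clock stood at 0.60 (percentile 78.6) and the Nr1d1 and Per arm at -0.61 (percentile 11.2), a sign that also turned. In the sex-linked list, not assessed as a whole, Xist, the RNA that coats the inactive X chromosome, was higher by 3.84. The lower value also lay below the mark for Foxj1, Hopx, Tbx5, Cdh17, Dcn, S100a8, Cd8b1, Pax5, Ptprc, Brca1, Mgmt, Egln3, Epha4, Tnfrsf10b, H2-Ab1, Cxcl3, Ccl5 and Ifit2, so these sizes are not exact; the bounds run down to 0.56 for Ifit2. Held at the mark, medians were -4.07 for club cells, -1.13 for ciliated cells, -0.92 for lung lineage regulators, -2.18 for fibroblasts and matrix, -1.22 for mesothelium, -0.93 for skeletal muscle, -0.70 for T cells, -0.02 for monocytes and interstitial macrophages, 0.00 for alveolar macrophages and -1.06 for the interferon response, where 8 genes stayed at least 2-fold lower. Of the 46 lists 10 were not assessed, and of the other 36, 21 lay outside the central 95% of random lists, and the sign of 7 of the 46 medians turned under at least 1 other scaling.

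**Figure D3:**
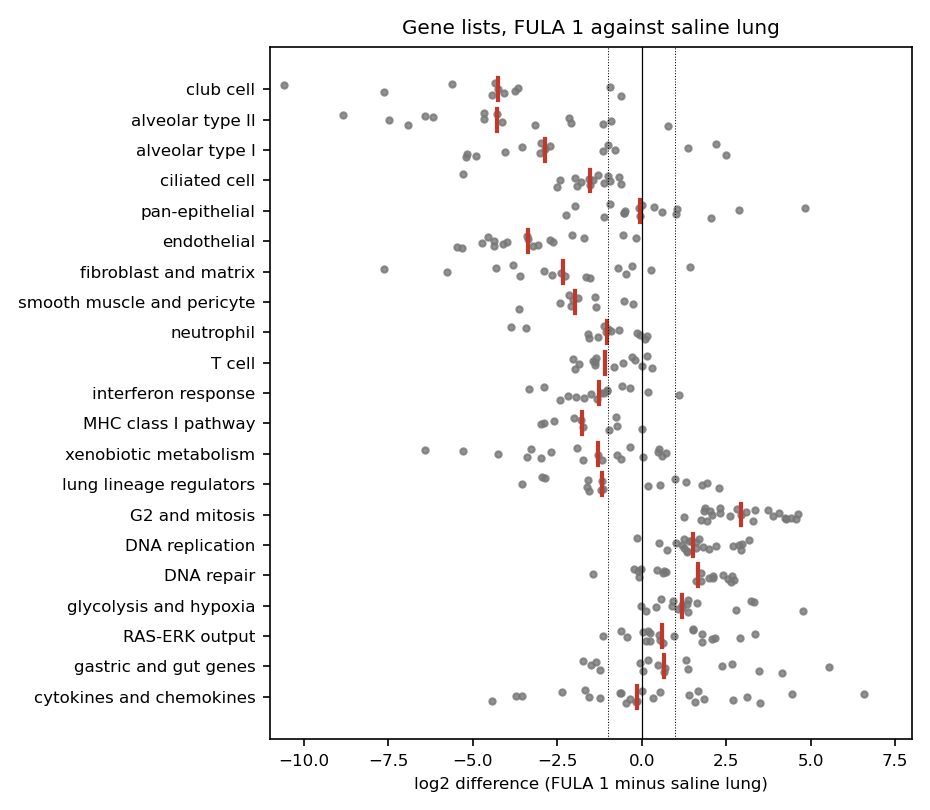
Log2 difference, FULA 1 minus saline lung (horizontal axis), of each measured member (grey points) of 21 gene lists, with the list median as a red bar and dotted lines at 2-fold. Medians run from -4.28 for alveolar type II markers to 2.93 for G2 and mitosis genes; the pan-epithelial sign turned under other scalings, and the neutrophil list shown was not assessed.

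Against the urethane lung, FULA 1 differed in much the same gene groups. Scgb1a1 was at -10.62 (log2, FULA 1 minus urethane) and Sftpc at -9.08, followed by Cbr2 at -7.82, Lyz1 at -7.62 and Inmt at -7.43. The highest were Clca3b at 7.33, Sprr1a at 6.57, Cxcl5 at 6.48, Ranbp3l at 6.27 and Anxa10 at 5.97. With the mark in place of a value below it, Scgb1a1 was lower by at least 9.92, and Cxcl5 was higher by at least 6.01, Clca3b by 5.90, Ranbp3l by 5.30 and Anxa10 by 4.81, so the order is not exact. All 23 G2 and mitosis genes were at least 2-fold higher, with a median of 2.99, Bub1 at 5.18 (at least 3.61) and Mki67 at 3.65. Among alveolar type II markers 15 of 15 were at least 2-fold lower, with a median of -4.26; Abca3, at -1.44, turned positive with the arrays shifted to a common median.

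Of 13264 genes past the floor, 2930 were at least 2-fold higher and 2581 at least 2-fold lower in FULA 1 than in the urethane lung. The values as deposited gave 21603 and 22, the shift to a common median 7154 and 1558, and lowess 2079 and 2931. Both FULA 1 comparisons share the FULA 1 array, so the likeness of their lists is not independent evidence.

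Many cell type lists, but not all, again lay below random lists. Their medians were -4.11 for club cells, -2.77 for alveolar type I, -1.88 for ciliated cells, -3.51 for endothelium, -2.29 for fibroblasts and matrix and -1.32 for mesothelium. Pan-epithelial genes, at 0.03 (percentile 53.7), lay inside the range. So did alveolar macrophages, at -0.55 (percentile 6.16), and dendritic cells, at -0.22 (percentile 35.4). In the smooth muscle and pericyte list, also below, 8 of 10 members were at least 2-fold lower, or 6 with values held at the mark, where ciliated cells stood at -1.56 and mesothelium at -1.04. Ager was at -5.36, Foxj1 at -2.29 (its FULA 1 value below the mark), Pecam1 at -4.29, Col1a1 at -4.31 and Ptprc at -1.73 (lower by at least 1.39). Cardiac muscle stood at -1.47, skeletal muscle at -0.83 and T cells at -1.03, each with a percentile under 1, though only at -0.78, -0.54 and -0.70 with values below the mark held at it. The lists of neutrophils, B cells and 9 others were not assessed. Also inside the range were gastric and gut genes, at 0.53 (percentile 97.1), which lay outside it with unmatched lists (98.8) or lists matched on the lungs (98.9) but whose median became 0.00 with values below the mark held at it. Above random lists lay DNA replication at 1.68, DNA repair at 1.61, glycolysis and hypoxia at 1.40, NRF2 targets at 1.13 (percentile 99.8) and RAS-ERK output at 0.84 (percentile 99.6). Held at the mark, DNA replication stood at 1.47, DNA repair at 1.10, glycolysis and hypoxia at 1.19 and NRF2 targets at 0.72, the last no longer outside the range. Below lay xenobiotic metabolism at -1.53, the interferon response at -1.19, MHC class II at -1.37, the MHC class I pathway at -1.90 and lung lineage regulators at -1.20. The Nr1d1 and Per arm of the clock was also below (percentile 0.150), with 5 of 9 members at least 2-fold lower, Hlf at -2.37 and Dbp at -1.84, and its sign turned with the arrays shifted to a common median. Cdkn1a was at -2.80, Xist at 3.92, Epcam at -1.28, turning positive under the same shift, and Cyp2e1 at -1.26 (lower by at least 0.80). In all, 11 of 46 lists were not assessed and 23 of the other 35 lay outside the central 95% of random lists, and the sign of 8 medians turned under at least 1 other scaling.

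The last comparison asked whether genes higher in the urethane lung than in the saline lung were also higher in FULA 1. Over 22180 genes, the covariance of urethane minus saline with FULA 1 minus saline was 0.158 (r = 0.311), of which the shared saline array gives 0.101 if the lungs differ by noise of equal size alone. With the midpoint of the lungs in place of the saline lung, where equal noise cancels, the covariance was 0.0565 (r = 0.116). With the urethane lung in its place it was -0.0450 (r = -0.0929). In a check chosen after the data were seen, the urethane minus saline difference of 1 probe set was set against the FULA 1 minus midpoint difference of the other probe set of the same gene. Over 968 genes with a pair of probe sets this correlation was 0.0245, inside the range of -0.0467 to 0.0428 that held the central 95% of 10000 shuffles, against 0.114 within the same probe set. Pairs of probe sets agreed little even past the floor (r = 0.103 over 315 genes for urethane minus saline). A shared direction could thus go unseen in this check. Unequal noise of the lung arrays was therefore not separated from a difference in the direction of the line.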

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

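The quantiles of the FULA 1 array, the floor at the olfactory receptor percentile, the values held at the olfactory receptor mark and the lung-matched lists were chosen after seeing the data, and the values as deposited were the plan's own setting. Without replicates, leaving out an array was not possible. No paired analysis was possible because each group has 1 array. Counts of genes at least 2-fold apart are given in the order urethane against saline (573), FULA 1 against saline (6067) and FULA 1 against urethane (5511). They were 2713, 9180 and 8614 at 1.5-fold and 18, 1619 and 1452 at 4-fold, as the threshold itself implies. They were 292, 3933 and 3643 with the floor at the 75th percentile, and 2613, 12485 and 11439 with all probe sets as units, which adds unnamed ones. The values as deposited gave 5180, 21723 and 21625, which carry the offset between arrays, and the offset of 32 gave 10, 822 and 763, since it shrinks low values. The quantiles of the FULA 1 array gave 1876 for urethane against saline, lowess gave 278, and the shift to a common median gave 8712 for FULA 1 against urethane; the cause was not tested. The other counts stayed within 1.5 times, which does not say that the same genes were counted.

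The position covariance of 0.0565 was 0.118 both with the shift to a common median and as deposited. These are 1 result, since a constant shift of an array leaves a covariance unchanged. The covariance was 0.00501 with the offset, 0.119 with the quantiles of FULA 1 and 0.0291 with lowess. What moved it from 0.0565 was not tested. By construction of the form, the covariance was 0.158 against the saline lung and -0.0450 against the urethane lung. With the arrays shifted to a common median, which leaves their curves as deposited, the alveolar type II median of urethane against saline became -0.17 and that of the Nr1d1 and Per arm in FULA 1 against urethane 0.18. Under the same shift 8 differences past 2-fold turned positive among the genes taken by the naming rule. They were Nras (0.11) and Nr1d1 (0.062) for FULA 1 against saline, and Epcam (0.069), Abca3 (0.13), Icam1 (0.34), Spry1 (0.53), Muc1 (0.11) and Ddit3 (0.63) for FULA 1 against urethane. Genes outside that rule were not counted, though some of them turned too, and the cause was not tested. Medians kept their sign under all 5 other scalings in 29, 39 and 38 of the 46 lists. Unmatched lists put 4, 25 and 26 lists outside the central range, and lung-matched ones 4, 25 and 27, against 3, 23 and 24, counting lists not assessed; values held at the mark put 6, 20 and 22 there, with many random medians at 0. The matching calls that differ are those of skeletal muscle and the Nr1d1 and Per arm for urethane against saline, NRF2 targets and RAS-ERK output for FULA 1 against saline, and mast cells and basophils, gastric and gut genes and the unfolded protein response for FULA 1 against urethane. Signal over background limits the lungs most, where 49.6% (saline) and 49.0% (urethane) of genes lay above the olfactory receptor mark.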

Other observations

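All tests in this part were chosen after the result was seen. A run of neighbouring genes, from Cdk6 to Tmem60 in the gene order of the RefSeq table, stood out in FULA 1. Cdk6, a kinase that drives entry into the cell cycle, was higher than the mean of the lungs by 1.83 (log2), Dbf4, which activates the replication kinase Cdc7, by 3.20, and the metalloreductase gene Steap2 by 3.16. The drug efflux pump genes Abcb1a and Abcb1b, near-identical to each other and therefore uncertain, were higher by 2.30 and 2.52, Cyp51, an enzyme of cholesterol synthesis, by 3.04, and the semaphorin gene Sema3e by 2.33. The run is not uniform: 13 of its 40 genes lay below 0, among them the fatty acid transporter gene Cd36 at -5.17 and Hgf at -1.56, and the sizes of Dbf4, Cyp51, Abcb1a and Abcb1b (below the background mark on both lungs), Steap2 (on the saline lung) and Hgf (on the saline lung and FULA 1) are not exact. At least 2-fold higher were 22 of the 40 (55.0%), against 20.8% of all 14069 genes placed.

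The run was the highest of 13289 windows of 40 genes, with a median of 1.61, and 0 of 100 shuffles of the gene order gave a window as high, the highest reaching 1.09. In all, 69 windows, which can overlap, lay above that highest shuffled window. Chance order is left open for this run even so, since 13 of the 40 genes lay below the mark on both lungs: with values below the mark held at it the median was 0.70, which 29 of 100 shuffles reached. Another window, from Kif20b to Arhgap19, was then the highest. Its median of 1.14 lay above the highest shuffled window held at the mark, 1.03, and it was not examined further. With genes that share a symbol stem counted once, the median over 32 stems was 1.01, below the highest shuffled window of 40 genes. This cannot decide whether clusters of related genes account for part of the excess. A shared stem need not mean related genes, since Tmem243 and Tmem60 were merged by name, and the shuffled windows were not reduced to stems. A gain of the DNA segment is a hypothesis left open, since DNA was not measured. In the run 26 of 40 genes were higher in FULA 1 than in both lungs. The run was picked for its high median, so this count cannot decide the question. Windows of 20 genes gave 1.97 from Mterf1a to Tmem243, against 1.56 in shuffles, and over 6 scalings the median of the run, relative to all genes, was between 0.25 and 2.23.

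Alveolar type II markers were higher in the urethane lung by a median of 0.37. More alveolar tissue in the sample cannot be told apart: the gap to the alveolar type I median was 0.36 (percentile 98.3 of random list pairs) after quantile normalization, but -0.11 (percentile 51.9, the lowest over 6 scalings) with the arrays shifted to a common median. Curvature of the array scale stays open: among random lists matched on lung expression the lowest percentile over 6 scalings was 75.2, with the arrays shifted to a common median, and the other 5 were at least 99.3. Urethane exposure cannot be told apart from a difference between individual lungs with 1 array per group.

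Immediate early and heat shock genes were higher in the urethane lung by a median of 0.46. Curvature of the scale is argued against, since the lowest percentile over 6 scalings was 99.9. Different times of day at sampling cannot be told apart from treatment: the gap of 0.45 between the medians of the clock arms stood at percentile 93.8 of random list pairs, neither outside their central range nor near its middle. Handling of the tissue and the treatment itself are untested and stay open.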
